A study of Mus musculus with 56 samples.

How the data were processed

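RNA sequencing was used to measure gene expression in the prefrontal cortex of 56 mice of the C57BL/6J strain, either heterozygous for Scn2a (HT) or wild type (WT). The mice had received fluoxetine, lithium or vehicle through maternal milk from postnatal day 3 to day 24, and the tissue was taken on day 25. Each library was placed in 1 of 12 groups by the genotype, treatment and sex in its title. The labels name no litter or dam. Because the drugs were given through the dam, pups of a group may have shared a mother. In that case the p-values of the drug effects below are too small. Those of genotype effects and interactions can be too small or too large, depending on whether HT and WT pups shared dams.

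Libraries were made with the TruSeq Stranded mRNA kit, per the labels' protocols. Salmon 0.11.2, R 3.6.0, DESeq2 1.19.11 and genome build GRCm38 are listed per the submitters' processing notes, which do not state the role of each, the annotation release or any filter. The deposited table held 18088 genes, and each value was a signal made by the authors by dividing a gene's read count by a single size factor per library. This was checked on the values: in every library 100% of the values were whole multiples of a common step, at a tolerance of 0.01 reads, which gave back the read counts and the size factors (0.818 to 1.23). In 3 libraries (HT lithium female 5, HT vehicle male 2 and HT vehicle male 5) the step lay too close to 1 for the test of whole reads to apply. Gene symbols were paired with 18077 of the Ensembl gene IDs, and coordinates are those of GENCODE release vM21 on GRCm38. Salmon assigns reads shared by near-identical sequences by a model, so values of ribosomal protein genes and of pseudogenes such as Rps4l, Eif4a-ps4 and Tpt1-ps3 are uncertain.

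The recovered depth was 24.3 to 36.4 M reads per library, with a median of 27.9 M. No 2 libraries were identical, and the correlation of log2 values between libraries ran from 0.977 to 0.99. Genes were tested if their value was at least 10 in at least 4 libraries, which kept 17778 genes and left out 310, 4 of them at 0 throughout. In R 4.3.3, limma 3.58.1 was fitted to log2(value + 1) with a mean for each of the 12 groups, and its moderated test used a trend of variance with expression and robust settings. All 56 libraries entered each fit. The drug and genotype effects were averaged over the sexes with equal weight, and each was also tested in females, in males and as the difference between them. Genotype effects were tested under each treatment, and the genotype by drug interaction was tested for both drugs. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. These adjusted p-values, each within a single comparison, are the ones given for genes.

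Fixed lists of genes, 38 in all, covering pathways, protein complexes, cell types and neighbouring brain regions, were tested against all other genes with camera in limma at a preset correlation of 0.01 between genes, over the 9 comparisons averaged over the sexes. The adjusted p-values given for lists are from camera. Because a preset correlation treats the genes of a list as nearly independent, camera was also run with a correlation estimated for each list. Counts "adjusted over the list alone" used the same tests with the adjustment made within the list. Scn2a was left out of its own list.

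The plan had listed edgeR on read counts as the test and limma for values already divided by size factors. The unit thus differed from what was assumed at the start, and the test planned for it was used. The groups, comparisons, test for each kind of unit, filter, gene lists and rule for naming genes were chosen before the data were examined. The rule named Scn2a, Scn1a, Scn3a and Scn8a. For each drug or vehicle genotype effect it named the 10 called genes with the smallest p and the 3 with the largest change in each direction, with a mean of at least 50 for the latter and predicted genes left out. Where no gene was called it named the 3 with the smallest p. It also named up to 4 members of each list with a call, and the 5 smallest p-values in each direction for other comparisons, or the single smallest where none was called. Some genes that this rule names are left out of the text and figures, while counts and list tests include them.

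Alternatives planned beforehand were TMM rescaling of the deposited values, limma with voom, no filter, pseudocounts of 0.5 and 5 in place of 1, only the groups compared, the replicate number as a block, leaving out each library in turn, and, for lists, the estimated correlation and fry. Chosen after the data were seen were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 (Wald test) on the recovered reads, covariates for olfactory and striatal marker scores, covariates for slopes of expression on transcript length and GC content, leaving out 14 libraries with such marker scores above 1, an exact permutation of list means within each sex, and the genotype effect pooled over treatments. A score was a library's mean log2 deviation over a marker list. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

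The procedure was tested on simulated data made from these libraries' means and depths. For lithium in WT, over 17778 genes, it called 26 of 50 genes changed 1.2-fold, 42 of 50 changed 1.5-fold, 47 of 50 changed 2-fold and 49 of 50 changed 3-fold, with 6 unchanged genes called. With no change simulated, it called 0 genes for the vehicle genotype effect and for fluoxetine in either genotype. Each gene was drawn independently, so the simulation holds no differences of dissection, litter or transcript length and GC content shared by many genes. False calls can therefore be more frequent in the real data. With labels exchanged at random among the real libraries, up to 31, 327 and 24 genes were called for the vehicle genotype effect and for fluoxetine in WT and HT.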

Results

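The prefrontal cortex of 56 mice was profiled on postnatal day 25. Scn2a encodes NaV1.2, a voltage-gated sodium channel of neurons, and the mice were heterozygous (HT) or wild type (WT) for it. They had been exposed for 3 weeks, through their mothers' milk, to fluoxetine, an antidepressant that blocks serotonin reuptake, to lithium, a mood stabiliser that inhibits glycogen synthase kinase 3 and inositol monophosphatase, or to vehicle. There were 5 libraries in each group of genotype, treatment and sex, except 4 in HT fluoxetine females, WT fluoxetine females, WT lithium females and WT vehicle males. Mean depth (± SD) under vehicle was 27.3 ± 2.59 M reads in HT females, 27.7 ± 2.21 M in HT males, 28.2 ± 1.77 M in WT females and 26.8 ± 2.66 M in WT males. Under fluoxetine it was 26.7 ± 1.23 M in HT females, 27.5 ± 2.28 M in HT males, 28.7 ± 1.88 M in WT females and 30.7 ± 3.61 M in WT males. Under lithium it was 27.6 ± 2.65 M in HT females, 27.3 ± 2.54 M in HT males, 27.0 ± 2.07 M in WT females and 28.5 ± 2.69 M in WT males. The sex genes matched the labels: Xist values were 14757 to 22868 in the 27 female libraries and 0 to 377 in the 29 male ones. The summed value of 4 Y genes was 3239 to 4569 in males and at most 2.36 in females except for 107 in WT fluoxetine female 4, which is 2.83% of the male median.

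Scn2a itself (ENSMUSG00000075318, chromosome 2, 65620771 to 65767447, plus strand) was measured in every group as a check of the genotype labels. Its value, in reads divided by the library's size factor, was 8554 ± 423 (SD, n = 29) in HT libraries and 12311 ± 780 (SD, n = 27) in WT libraries. The ranges, 7583 to 9619 and 9727 to 13381, did not overlap. Under vehicle the means were 8138 ± 316 (SD, n = 5) in HT females, 8611 ± 198 (n = 5) in HT males, 11599 ± 1218 (n = 5) in WT females and 12607 ± 579 (n = 4) in WT males. Under fluoxetine they were 8783 ± 328 (n = 4) in HT females, 8555 ± 214 (n = 5) in HT males, 12298 ± 584 (n = 4) in WT females and 12212 ± 832 (n = 5) in WT males. Under lithium they were 8536 ± 748 (n = 5) in HT females, 8744 ± 334 (n = 5) in HT males, 12721 ± 450 (n = 4) in WT females and 12570 ± 363 (n = 5) in WT males. Neither drug changed Scn2a past the threshold, with log2 changes of 0.02 and 0.05 for fluoxetine in WT and HT (adjusted p = 0.89 and 0.72) and of 0.07 and 0.04 for lithium (adjusted p = 0.29 and 0.49).

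**Figure D1:**
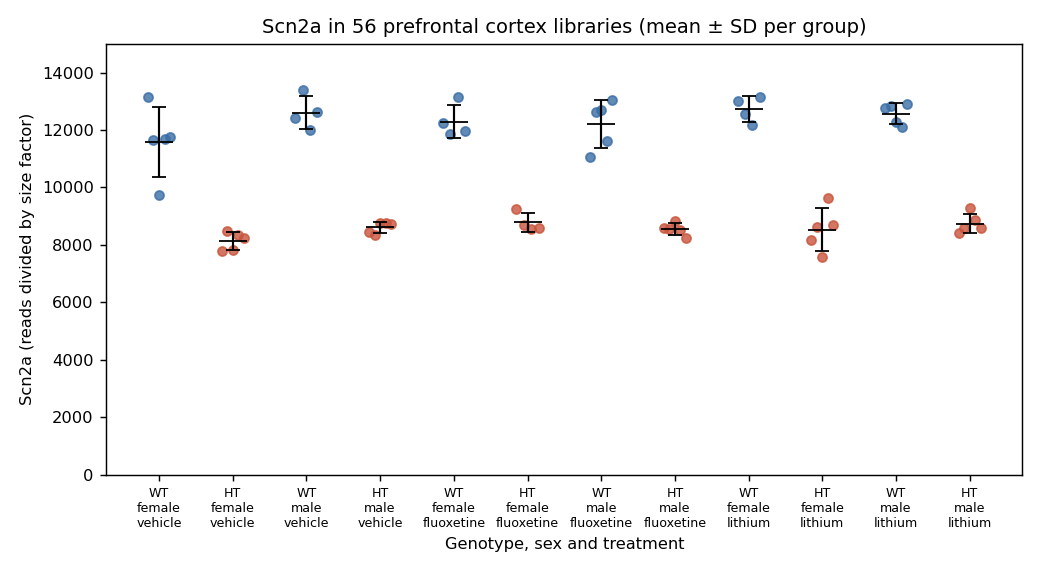
Scn2a in reads divided by the size factor, from 0 on the vertical axis, for each library (points) of the 12 groups on the horizontal axis, with the mean and SD per group as bars. The 29 HT libraries lie between 7583 and 9619, below the 27 WT libraries at 9727 to 13381.

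The genotype effect under vehicle asked what loss of a functional Scn2a copy did to the untreated cortex. Scn2a was the single gene called. It fell by 0.53 ± 0.037 on the log2 scale (SE), a change of -30.6%, in 10 of 10 HT libraries (adjusted p = 4.6e-15). It fell in females (-0.51, adjusted p = 2.6e-09) and in males (-0.55, adjusted p = 1.2e-09). The other sodium channel genes of the brain did not pass the test. Scn1a, which neighbours Scn2a on chromosome 2 and serves inhibitory neurons, had a log2 change of -0.15 (adjusted p = 0.32). The values were -0.07 for Scn8a (adjusted p = 0.56) and 0.00 for Scn3a (adjusted p = 1). The smallest p-values above the threshold belonged to Fxyd6, a regulator of the sodium pump (0.20 ± 0.041, adjusted p = 0.066, higher in 10 of 10 HT libraries). Next were Eef1a1, a translation elongation factor (0.13, adjusted p = 0.095), and Zwint (0.13, adjusted p = 0.095). Cholesterol biosynthesis genes rose as a list (22 of 24 higher, median 0.06, adjusted p = 1.3e-05, or adjusted p = 0.70 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone. Proteasome genes rose likewise (39 of 43, median 0.04, adjusted p = 3.4e-08, or adjusted p = 0.70 with an estimated correlation). Chromatin regulators (39 of 51 lower, median -0.03, adjusted p = 2.8e-05), interferon response genes (28 of 30 lower, median -0.07, adjusted p = 0.0069) and voltage-gated calcium channels (11 of 15 lower, median -0.06, adjusted p = 0.0093) fell. All 10 list calls here were lost with an estimated correlation (adjusted p of 0.70 to 0.86 with an estimated correlation), and none was refitted with length and GC slopes. The HT vehicle libraries also enter the drug effects in HT and the interactions, which alone brings opposite changes there. Across genes this genotype effect correlated at r = -0.429 with fluoxetine and -0.330 with lithium in HT. Groups simulated without an effect on the same libraries gave -0.503 and -0.493. The count of 1 gene became 34 with DESeq2, 3 with voom, 13 with the tissue scores as covariates, and 2 with length and GC slopes or without the 14 libraries with olfactory or striatal transcripts. It was 35 without HT vehicle female 1, and 12 without WT fluoxetine male 5. It was 4 without HT vehicle male 1, WT vehicle female 4 or WT vehicle male 2, 3 without WT vehicle female 3 or WT vehicle male 3, and 2 without HT vehicle female 3.

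Few genes were called for fluoxetine in WT mice. Tsc22d3, the glucocorticoid-induced leucine zipper, rose by 41.3% (log2 change 0.50 ± 0.11 SE, adjusted p = 0.048, 8 of 9 libraries). Slc2a1, the glucose transporter of brain capillaries and astrocytes, rose by 37.9% (0.46 ± 0.101, adjusted p = 0.048, 9 of 9). Creld2, a chaperone induced by stress of the endoplasmic reticulum, rose by 35.7% (0.44 ± 0.096, adjusted p = 0.048, 9 of 9). Insig1, which holds the sterol sensor in the endoplasmic reticulum, fell (-0.31 ± 0.060, a change of -19.1%, adjusted p = 0.024, 8 of 9), as did Stard4, a cholesterol transport protein (-0.27 ± 0.060, adjusted p = 0.048, 9 of 9). The largest decrease among the named genes was that of Tnfsf10, the death ligand TRAIL, at -0.87 ± 0.198 (adjusted p = 0.048, 8 of 9), on a low mean value of 61.6. The smallest p belonged to Rbm17, a splicing factor (0.16 ± 0.031, adjusted p = 0.016, 9 of 9). Other named genes that rose were Hacd3, Zfp143, Paqr8, Taf3, Hdgf and Epc2 (0.10 to 0.24). Others that fell were Cep164 (-0.23), Kmt2d, a histone methyltransferase (-0.20), and Rnf213 (-0.31). The adjusted p was 0.044 for Hacd3 and 0.048 for the rest.

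In total 26 genes were called for fluoxetine in WT, 18 higher and 8 lower. Glucocorticoid-responsive genes rose as a list (17 of 20 higher, median 0.26, adjusted p = 3.5e-12, or adjusted p = 0.16 with an estimated correlation). Called over all genes were 2 of them, Tsc22d3 and Klf9 (0.22 ± 0.050, adjusted p = 0.048), and 12 adjusted over the list alone. Members that missed the threshold were Zbtb16 (0.62, adjusted p = 0.054) and Fkbp5 (0.48, adjusted p = 0.096). Heat shock and unfolded protein response genes rose (27 of 30, median 0.11, adjusted p = 2.1e-16, or adjusted p = 0.16 with an estimated correlation). Creld2 was called, and 18 passed adjusted over the list alone. Cholesterol biosynthesis genes fell (22 of 24, median -0.11, adjusted p = 1.4e-11, or adjusted p = 0.22 with an estimated correlation). Insig1 and Stard4 were called, and 12 passed adjusted over the list alone. Interferon response genes fell (27 of 30, median -0.13, adjusted p = 2.1e-05, or adjusted p = 0.22 with an estimated correlation), with 0 called by limma over all genes or over the list alone. Npas4, an immediate early gene, had a log2 change of -0.75 ± 0.175 that missed the threshold (adjusted p = 0.056). Of 100 splits of these libraries, 6 called as many genes as the treatment did. DESeq2 called 123, the fit with tissue scores as covariates 66, that with length and GC slopes 57, voom 7, the fit of the compared groups alone 9, and the fit without the 14 libraries with olfactory or striatal transcripts 8. The count moved by more than 1.5 times on the omission of 36 of the 56 libraries taken singly. It was 0 without WT vehicle male 1, 1 without WT fluoxetine female 2, 2 without WT vehicle male 4, and 3 without WT vehicle female 2 or 5. It was 4 without HT fluoxetine female 2 or male 5, HT lithium female 2 or 5 or male 2, HT vehicle male 2 or 3, WT fluoxetine female 3 or 4 or male 5, WT lithium female 1 or 3 or male 1 or 3, or WT vehicle female 1 or 3. It was 5 without HT fluoxetine male 1, 2, 3 or 4, HT vehicle female 2 or male 1, WT fluoxetine male 4 or WT lithium male 4. It was 6 without HT fluoxetine female 4, 7 without HT vehicle male 4 or 5, 8 without WT fluoxetine male 3, and 10 without WT fluoxetine male 2. It rose to 47 without WT fluoxetine female 1 and to 71 without WT fluoxetine male 1. The calls of Rbm17 and Insig1 were lost in 3 and 8 of these omissions (highest adjusted p = 0.095 and 0.10, both without WT fluoxetine female 2), and those of the other named genes in 21 to 40.

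In HT mice fluoxetine lowered cholesterol biosynthesis genes. Stard4 (chromosome 18, 33199355 to 33213862) fell from 991 ± 72.0 (SD, n = 5) to 764 ± 97.1 (n = 4) in females and from 1004 ± 31.5 (n = 5) to 779 ± 37.0 (n = 5) in males, a log2 change of -0.37 ± 0.058 (SE, adjusted p = 0.0011). Insig1 (chromosome 5, 28071363 to 28078662) fell from 2149 ± 40.2 (SD, n = 5) to 1633 ± 127 (n = 4) in females and from 2165 ± 103 (n = 5) to 1762 ± 134 (n = 5) in males, a log2 change of -0.35 ± 0.058 (SE, adjusted p = 0.002). Fdps, which makes farnesyl diphosphate (-0.31, adjusted p = 0.0051), Sqle, the squalene epoxidase (-0.29, adjusted p = 0.014), and Mvk, the mevalonate kinase (-0.22, adjusted p = 0.036), fell as well. Acat2, the cytosolic thiolase that supplies acetoacetyl-CoA, lies outside the list and fell by 0.26 (adjusted p = 0.015). Outside this pathway, Rps4l, a transcribed processed pseudogene of a ribosomal protein that the list of cytosolic ribosomal proteins counts as a member, fell by 0.51 (adjusted p = 0.015). Each of the 8 called genes was lower in 9 of 9 fluoxetine libraries.

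All 24 genes of the cholesterol list had lower values under fluoxetine in HT (median -0.21, adjusted p = 3e-42), 6 of them called over all genes and 22 adjusted over the list alone. This list kept its call with an estimated correlation (adjusted p = 0.00098 with an estimated correlation), and in an exact permutation of its mean (adjusted p = 0.0012). Over the 9 comparisons it was the only camera call of any list that held with an estimated correlation. Cytosolic ribosomal protein genes (80 of 82 lower, median -0.07, adjusted p = 1.3e-19) and oxidative phosphorylation genes (69 of 79 lower, median -0.04, adjusted p = 4.5e-07) fell, each with adjusted p = 0.70 with an estimated correlation. Voltage-gated potassium channels rose (28 of 35, median 0.05, adjusted p = 0.00038, or adjusted p = 0.66 with an estimated correlation). Astrocyte markers were lower at the same time (22 of 25, median -0.05, adjusted p = 0.0031, or adjusted p = 0.70 with an estimated correlation). So were olfactory bulb and migrating neuroblast markers (17 of 17, median -0.26, adjusted p = 0.045, or adjusted p = 0.71 with an estimated correlation). No gene was called as higher, and the smallest p-values in that direction were those of Ppp1r10 (0.15, adjusted p = 0.080), Rsph10b (0.30, adjusted p = 0.12) and Cnot2 (0.10, adjusted p = 0.17). The count of 8 became 16 with DESeq2, 13 with the tissue scores as covariates, 5 with length and GC slopes as covariates and 19 in the fit of the compared groups alone. It was 2 without the 14 libraries with olfactory or striatal transcripts, 13 without WT fluoxetine male 5, 4 without HT fluoxetine female 2 or HT vehicle female 5, and 5 without HT fluoxetine female 1 or HT fluoxetine male 5. The call of Mvk was lost in 12 single omissions (highest adjusted p = 0.14, without HT vehicle female 5) and that of Acat2 in 5 (0.059, without HT fluoxetine female 1). The call of Rps4l was lost in 4 (0.073, without HT fluoxetine male 5) and that of Sqle in 3 (0.053, without HT fluoxetine female 2).

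**Figure D2:**
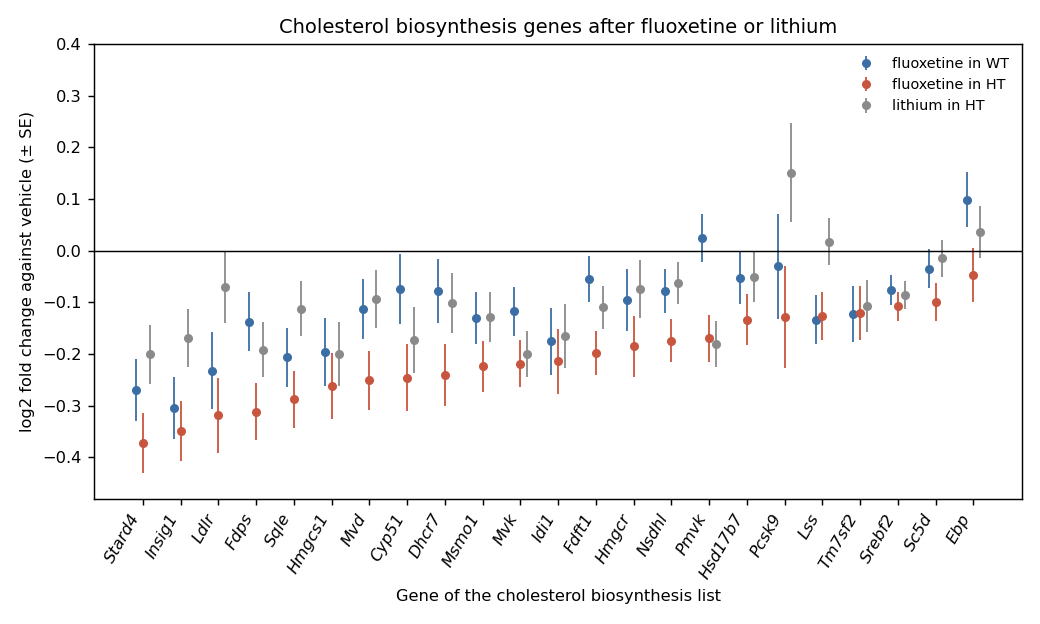
Log2 change against vehicle (vertical axis, points with SE bars) for genes of the cholesterol biosynthesis list (horizontal axis), for fluoxetine in WT, fluoxetine in HT and lithium in HT. All genes shown lie below 0 for fluoxetine in HT, and most do for fluoxetine in WT and lithium in HT.

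Whether fluoxetine acted differently in the 2 genotypes was tested by the interaction. It called 0 genes with limma, edgeR, voom and DESeq2, and limma gave 967 genes at an unadjusted p under 0.05. The smallest p was that of Gabre, a GABA-A receptor subunit with a mean value of 9 (-1.42, adjusted p = 0.81). The called genes of the genotypes shared Stard4 and Insig1 among the lower ones, against 0.0036 shared by chance between independent lists. That value treats genes as independent and is too small here, since both belong to the cholesterol list, whose genes fell together. Across the 17778 genes, which are not independent replicates, the log2 changes in WT and HT correlated at r = 0.0631, inside the -0.196 to 0.166 of simulated groups without an effect, and 58.1% had the same sign. The genes of the cholesterol list had more negative values in HT by a median of -0.09 (22 of 24, adjusted p = 1.3e-06, or adjusted p = 0.66 with an estimated correlation). Those of the glucocorticoid list were lower in HT relative to WT by -0.22 (20 of 20, adjusted p = 1.3e-06, or adjusted p = 0.50 with an estimated correlation).

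Lithium in WT mice changed many genes, most of them by small amounts. Ctnnb1, which encodes beta-catenin, the protein that glycogen synthase kinase 3 marks for degradation, fell by 0.17 ± 0.027 on the log2 scale (SE, adjusted p = 2e-04, 9 of 9 libraries). Frat1, which encodes a protein that binds the same kinase, fell by 0.50 ± 0.072 (adjusted p = 4.8e-05, 8 of 9). Pnck, a calcium and calmodulin dependent kinase on chromosome X, fell by 0.43 ± 0.059 (a change of -26.0%, adjusted p = 2.6e-05, 9 of 9). Ncdn, a neuronal protein involved in neurite outgrowth, rose by 0.17 ± 0.024 (adjusted p = 4.8e-05), Chgb, the secretory granule protein chromogranin B, by 0.28 ± 0.043 (adjusted p = 2e-04) and Nefh, the heavy neurofilament subunit, by 0.29 ± 0.046 (adjusted p = 2e-04), each in 9 of 9 libraries. Timp2, an inhibitor of metalloproteinases, Dnaja4, a co-chaperone, Rab11fip3 and Wipf3 rose by 0.13 to 0.39. Within the same range rose Atp6ap1, a subunit of the proton pump of lysosomes and vesicles, Castor2 of the mTORC1 pathway and the lysosomal protease Ctsa. Ly86, a partner of the immune receptor Cd180, fell by 0.33 ± 0.053 (adjusted p = 2e-04). The ribosomal protein genes Rpl9, Rpl17, Rps10, Rps27a and Rpl13a fell by values from -0.18 to -0.32, with BC029722 at -0.20. Among called genes with a mean of at least 50, predicted genes left out, the largest increases were those of the pseudogene Eif4a-ps4 (1.53 ± 0.410, adjusted p = 0.022) and the transcription factors Zbtb16 (0.63 ± 0.144, adjusted p = 0.0082) and Hif3a (0.57 ± 0.177, adjusted p = 0.045). The largest decreases under the same limit were those of Tnfsf10 (-0.71, adjusted p = 0.025), the mitochondrial gene mt-Nd3 (-0.66, adjusted p = 0.047) and Cd180 (-0.60, adjusted p = 0.047).

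In total 1016 genes were called for lithium in WT, 682 higher and 334 lower, or 67.1% higher. With TMM rescaling 55.9% of the calls were higher (494 of 884), and with voom 316 of 794 were. Dropping single libraries gave 571 to 1226 calls. There were 571 without WT vehicle male 1, 597 without WT lithium female 4, 602 without WT vehicle male 4 and 618 without WT vehicle female 3. Length and GC slopes as covariates gave 1686 calls, and the fit without the 14 libraries with olfactory or striatal transcripts gave 457. The call of Cd180 was lost in 23 single omissions (highest adjusted p = 0.13, without WT lithium female 4), that of mt-Nd3 in 20 (0.11, without WT lithium female 3). The call of Hif3a was lost in 13 (0.094, without WT lithium female 4), that of Tnfsf10 in 3 (0.064, without WT lithium female 4) and that of Eif4a-ps4 in 1 (0.083, without WT vehicle male 1).

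Several of the fixed lists moved under lithium in WT. Cytosolic ribosomal protein genes fell (75 of 82, median -0.14, adjusted p = 4.3e-25, or adjusted p = 0.29 with an estimated correlation). Over all genes 31 of them were called, and 46 adjusted over the list alone. Microglia markers fell (23 of 24, median -0.17, adjusted p = 1.5e-10, or adjusted p = 0.29 with an estimated correlation), with 6 called and 15 adjusted over the list alone. Among them were Ly86, Tyrobp (-0.27, adjusted p = 0.011) and Siglech (-0.25, adjusted p = 0.014). Heat shock and unfolded protein response genes rose (28 of 30, median 0.15, adjusted p = 1.5e-12, or adjusted p = 0.29 with an estimated correlation), with 12 called and 21 adjusted over the list alone. Examples were Hyou1 (0.22, adjusted p = 0.0012), Herpud1 (0.33, adjusted p = 0.0013) and Hsp90ab1 (0.10, adjusted p = 0.015). Genes of inositol phosphate metabolism, which holds a direct target of lithium, rose slightly (23 of 24, median 0.05, adjusted p = 0.0016, or adjusted p = 0.29 with an estimated correlation). Cdipt (0.11, adjusted p = 0.0099) and Pi4ka (0.12, adjusted p = 0.022) were called, the same 2 adjusted over the list alone. Impa1, an inositol monophosphatase, had a change of 0.06 (adjusted p = 0.091).

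Meningeal and fibroblast markers were lower in the same libraries (18 of 19, median -0.26, adjusted p = 2.4e-07, or adjusted p = 0.35 with an estimated correlation). Col3a1 (-0.41, adjusted p = 0.028), Igf2 (-0.32, adjusted p = 0.038) and Slc6a13 (-0.38, adjusted p = 0.047) were called, and 12 adjusted over the list alone. Glucocorticoid-responsive genes rose (18 of 20, median 0.22, adjusted p = 4.9e-05, or adjusted p = 0.35 with an estimated correlation), with 5 called and 6 adjusted over the list alone. They included Zbtb16, Tsc22d3 (0.50, adjusted p = 0.0062), Klf9 (0.20, adjusted p = 0.012) and Sgk1 (0.25, adjusted p = 0.042). Clock genes rose (16 of 21, median 0.08, adjusted p = 0.00099, or adjusted p = 0.35 with an estimated correlation). Hlf (0.19, adjusted p = 0.007) and Ciart (0.32, adjusted p = 0.025) were called, and 10 rose adjusted over the list alone. Voltage-gated potassium channels rose (27 of 35, median 0.06, adjusted p = 0.0024, or adjusted p = 0.35 with an estimated correlation). Kcna1 (0.28, adjusted p = 0.0044) and Kcnab3 (0.22, adjusted p = 0.046) were among those called, and 7 adjusted over the list alone. Interferon response genes fell (25 of 30, median -0.11, adjusted p = 0.0012, or adjusted p = 0.35 with an estimated correlation). Psmb8 (-0.44, adjusted p = 0.014) and Isg15 (-0.41, adjusted p = 0.046) were called, also adjusted over the list alone. Presynaptic vesicle genes rose (25 of 31, median 0.06, adjusted p = 0.00017, or adjusted p = 0.55 with an estimated correlation). They were led by the fusion clamp Cplx1 (0.17, adjusted p = 0.001) and the vesicle protein Sv2a (0.15, adjusted p = 0.0014), although Rims1 of the release site fell (-0.20, adjusted p = 0.011). Immediate early genes rose (26 of 30, median 0.18, adjusted p = 0.0079, or adjusted p = 0.73 with an estimated correlation), with Bdnf alone called (0.34, adjusted p = 0.037). Cholesterol biosynthesis genes rose (20 of 24, median 0.07, adjusted p = 0.0032, or adjusted p = 0.68 with an estimated correlation). Sc5d (0.15, adjusted p = 0.016) and Ebp (0.19, adjusted p = 0.026) were called, and 3 adjusted over the list alone. Targets of Wnt and beta-catenin signalling did not pass the test as a list (16 of 19 lower, median -0.09, adjusted p = 0.055), with 0 of 19 called by limma. Axin2, a direct target, had log2 changes of 0.01 in WT (adjusted p = 0.93) and 0.05 in HT (adjusted p = 0.50).

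**Figure D3:**
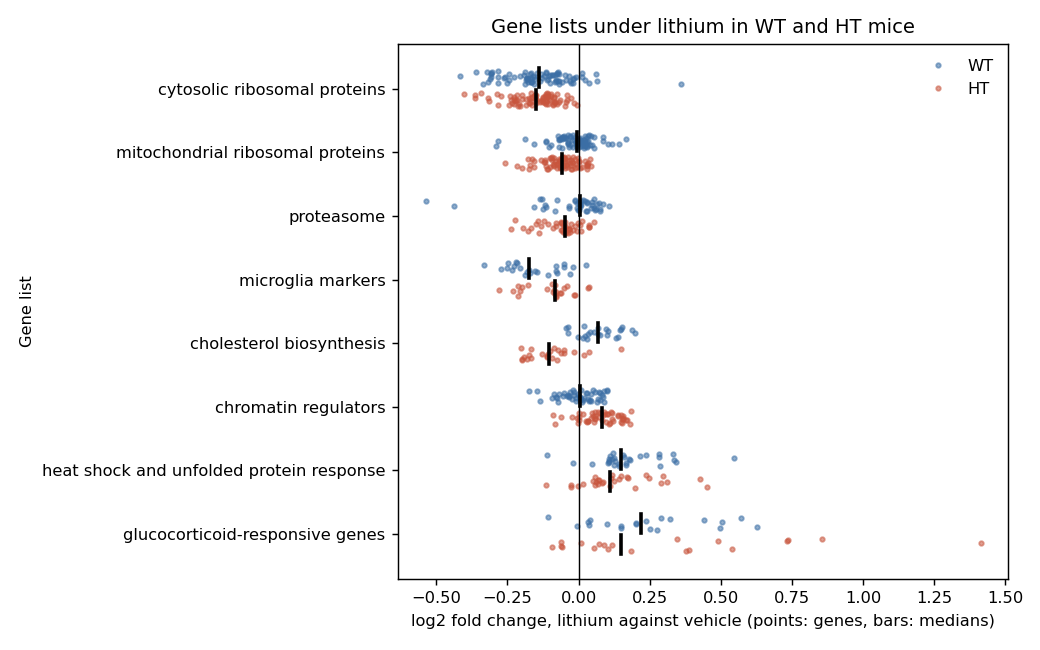
Log2 change of each member of selected gene lists (points) under lithium in WT and in HT, on the axis of log2 change against vehicle, with the median of each list marked. Cytosolic ribosomal protein genes have medians of -0.14 in WT and -0.15 in HT.

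Lithium in HT mice again lowered Ctnnb1 and Pnck. Ctnnb1 (chromosome 9, 120929216 to 120960507) fell from 18527 ± 757 (SD, n = 5) to 15422 ± 414 (n = 5) in females and from 18165 ± 842 (n = 5) to 15313 ± 930 (n = 5) in males, a log2 change of -0.26 ± 0.025 (SE, adjusted p = 2.3e-09). Pnck (chromosome X, 73655994 to 73660117) fell from 1638 ± 133 (SD, n = 5) to 1200 ± 130 (n = 5) in females and from 1661 ± 261 (n = 5) to 1185 ± 104 (n = 5) in males, a log2 change of -0.47 ± 0.055 (SE, adjusted p = 3.7e-07). Both were lower in 10 of 10 libraries, and Frat1 fell by 0.35 (adjusted p = 8e-04). Cpeb1, a regulator of mRNA polyadenylation and translation at synapses, rose by 0.29 ± 0.037 (adjusted p = 8.3e-07, 10 of 10). Fnip2, Wipf3, Ctsa, Igf2r, which carries lysosomal enzymes, Ift80, Vwa8, Nvl and Ankhd1 rose by 0.16 to 0.43, each in 10 of 10 libraries. Eif4h, a translation initiation factor (-0.22, adjusted p = 7.2e-07), Spop, a ubiquitin ligase adaptor (-0.19, adjusted p = 2.5e-05), Emc7, Dmac1, Wdr13, Fbll1, Nanos1 and Tmem91 fell by values from -0.16 to -0.46. Among called genes with a mean of at least 50, predicted genes left out, the largest increases were those of Etnppl, an enzyme of astrocytes that breaks down phosphoethanolamine (1.34 ± 0.330, adjusted p = 0.0077, 9 of 10), Hif3a (0.74 ± 0.167, adjusted p = 0.0039) and Map3k6 (0.73 ± 0.175, adjusted p = 0.0057). The largest decreases under the same limit were those of 3 genes of endothelial cells, the apelin receptor Aplnr (-1.19 ± 0.293, adjusted p = 0.0072, 9 of 10), the amino acid transporter Slc38a5 (-0.57, adjusted p = 0.0048) and Ecscr (-0.57, adjusted p = 0.00028).

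In total 1560 genes were called for lithium in HT, 825 higher and 735 lower, or 52.9% higher against 51.5% with TMM rescaling. Voom called 973 of 1568 as higher. Leaving out HT lithium male 3 gave 985 calls and leaving out HT lithium female 5 gave 1023. Length and GC slopes as covariates gave 58 calls, 50 of them shared with the 1560. The fit without the 14 libraries with olfactory or striatal transcripts gave 586.

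All 82 genes of the cytosolic ribosomal protein list, Rps4l included, had lower values under lithium in HT (median -0.15, adjusted p = 8.4e-30, or adjusted p = 0.54 with an estimated correlation). With length and GC slopes as covariates the difference in the list mean moved from -0.157 ± 0.0393 to -0.0604 ± 0.0323 (SE), and 2 libraries stood apart from their groups on this score, HT lithium male 3 at -0.247 and HT vehicle male 5 at -0.130. The length slopes themselves differed, from -0.0529 to 0.00283 in HT vehicle and from -0.0154 to 0.0530 in HT lithium libraries. The other lists of this paragraph were not refitted with these slopes, so a length or GC trend was not tested for them. Over all genes 42 were called and 68 adjusted over the list alone, among them Rps10 (-0.32, adjusted p = 0.00021) and Rpl9 (-0.20, adjusted p = 0.001). Chromatin regulators rose (45 of 51, median 0.08, adjusted p = 3.5e-09, or adjusted p = 0.54 with an estimated correlation), with 14 called as higher and 19 adjusted over the list alone. The remodeller Chd8, mutated in autism, was among them (0.15, adjusted p = 0.00038), as was Chd4 (0.11, adjusted p = 0.00084), whereas Chd3 fell (-0.08, adjusted p = 0.0053). Oxidative phosphorylation genes (72 of 79, median -0.06, adjusted p = 8.7e-10, 8 called, 19 adjusted over the list alone), mitochondrial ribosomal protein genes (66 of 78, median -0.06, adjusted p = 1.1e-07, 10 called, 12 adjusted over the list alone) and proteasome genes (36 of 43, median -0.05, adjusted p = 1.7e-06, 6 called, 13 adjusted over the list alone) fell, each with adjusted p = 0.54 with an estimated correlation. Cholesterol biosynthesis genes fell (21 of 24, median -0.10, adjusted p = 3.3e-06, or adjusted p = 0.54 with an estimated correlation), with 7 called and 11 adjusted over the list alone. Among these were Mvk (-0.20, adjusted p = 0.0032) and Stard4 (-0.20, adjusted p = 0.019). Heat shock and unfolded protein response genes rose (26 of 30, median 0.11, adjusted p = 3.9e-06, or adjusted p = 0.54 with an estimated correlation), with 7 called and 10 adjusted over the list alone, Hyou1 (0.17, adjusted p = 0.0022) and Pdia4 (0.31, adjusted p = 0.0084) among them. Microglia markers fell (22 of 24, median -0.08, adjusted p = 7e-05, or adjusted p = 0.54 with an estimated correlation), with 5 called and 6 adjusted over the list alone, including Fcrls (-0.28, adjusted p = 0.0048) and P2ry12 (-0.21, adjusted p = 0.036). Glucocorticoid-responsive genes rose (16 of 20, median 0.15, adjusted p = 0.00011, or adjusted p = 0.54 with an estimated correlation), with 7 called and 8 adjusted over the list alone, Plin4 (1.41, adjusted p = 0.008) and Zbtb16 (0.54, adjusted p = 0.0086) among them. Autism risk genes rose (71 of 95, median 0.04, adjusted p = 0.0015, or adjusted p = 0.54 with an estimated correlation), with 12 called as higher and 5 as lower. Endothelial and pericyte markers fell (20 of 28, median -0.10, adjusted p = 0.0019, or adjusted p = 0.62 with an estimated correlation). Cldn5, a tight junction protein (-0.49, adjusted p = 0.0025), and Kdr, a receptor for vascular growth factor (-0.45, adjusted p = 0.006), were called as lower and Flt1 as higher (0.19, adjusted p = 0.011).

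**Figure D4:**
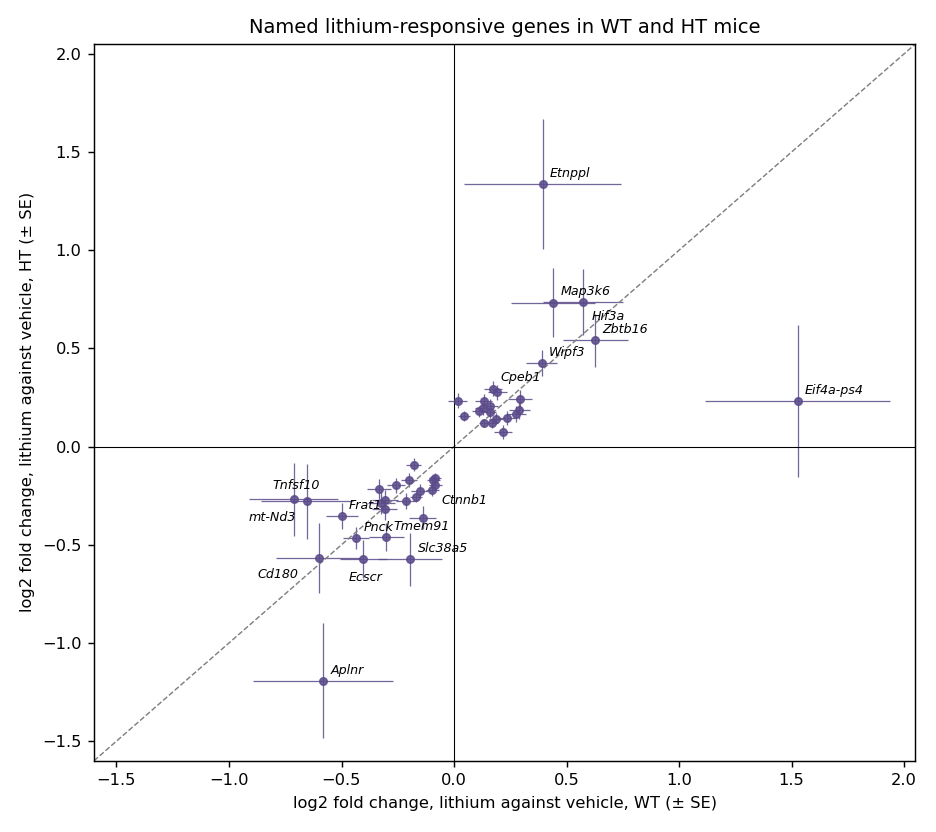
Log2 change under lithium in WT (horizontal axis) and in HT (vertical axis) for the named lithium genes, each with SE bars in both directions. Ctnnb1 lies at -0.17 and -0.26 and Pnck at -0.43 and -0.47.

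The responses to lithium in the 2 genotypes were compared directly. The genotype by lithium interaction called 0 genes with limma, edgeR and voom and 11 with DESeq2, all higher. Limma gave 1934 genes at an unadjusted p under 0.05. Its smallest p was that of Pou2f2, a transcription factor (0.45, adjusted p = 0.16), and 1 gene was called without HT lithium female 4. Both genotypes shared 200 called genes among the higher ones and 116 among the lower ones, against 31.6 and 13.8 for independent lists. The latter values treat genes as independent, which they are not. Of the 1016 genes called in WT, 917 (90.3%) had the same sign in HT, and of the 1560 called in HT, 1345 (86.2%) had the same sign in WT. Over all 17778 genes 61.1% had the same sign. The slope of the log2 changes was 0.354 for HT on WT over genes called in WT, and 0.384 for WT on HT over those called in HT. Genes called in a genotype are picked partly for large values there. Slopes below 1 would therefore arise even with equal effects, and they show no difference between genotypes. Across all 17778 genes the correlation was r = 0.230, above the -0.269 to 0.197 of simulated groups without an effect. The simulated groups exchanged single libraries and hold no shared dams. If WT and HT pups shared dams, a litter effect could give such agreement, and this could not be tested. So could a length trend shared by the lithium libraries of both genotypes. The length slopes ran from -0.0133 to 0.0189 in WT vehicle and from -0.0119 to 0.0497 in WT lithium libraries. In HT they ran from -0.0529 to 0.00283 under vehicle and from -0.0154 to 0.0530 under lithium. The agreement was not recomputed with these slopes as covariates. The covariance was 0.00858, against a simulated -0.000447. Cholesterol biosynthesis genes, higher in WT and lower in HT under lithium, differed by a median of -0.17 (24 of 24, adjusted p = 4.7e-13, or adjusted p = 0.47 with an estimated correlation), with 14 of them past the threshold adjusted over the list alone.

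Fluoxetine and lithium were set beside each other within each genotype. In WT they shared 10 called genes that were higher, among them Slc2a1, Tsc22d3, Klf9 and Paqr8 (0.691 for independent lists), and 2 that were lower, Tnfsf10 and Rnf213 (0.15). In HT they shared 5 lower genes, Stard4, Mvk, Insig1, Fdps and Rps4l (0.331). These comparisons use the same vehicle libraries, which alone bring correlated changes. The values for independent lists allow neither for this nor for genes that move together. The correlation across genes was r = 0.476 in WT, where unchanged groups simulated against the same controls gave 0.494, and 0.474 in HT, where they gave 0.495. The covariance was 0.0172 in WT against 0.0140 simulated, and 0.0145 in HT against 0.0134 simulated. With the vehicle libraries split between the drugs, the correlations were 0.00712 and 0.15 in WT and 0.0555 and -0.00467 in HT.

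Under each drug the genotype effect was again led by Scn2a. It fell by 0.50 under fluoxetine (a change of -29.2%, adjusted p = 1.3e-13, 9 of 9 HT libraries) and by 0.55 under lithium (-31.8%, adjusted p = 7.4e-16, 10 of 10). Under fluoxetine the other called gene was Grin3a, an NMDA receptor subunit (0.18 ± 0.033 SE, adjusted p = 0.016, higher in 9 of 9). Its call was lost without HT fluoxetine female 4, HT fluoxetine male 3, WT fluoxetine female 1, WT fluoxetine female 4 or WT fluoxetine male 1, each of which left 1 call. Under lithium 6 genes were called, all lower in HT. They included Tph2, the enzyme that limits serotonin synthesis in neurons (-1.35 ± 0.228, a change of -60.6%, adjusted p = 0.0028, on a mean of 26), and the actin regulator Rflnb (-0.34, adjusted p = 0.014). Others were Heg1 (-0.20, adjusted p = 0.020) and Acvrl1 (-0.25, adjusted p = 0.023), both receptors of blood vessel cells, each lower in 10 of 10 HT libraries. The calls were lost in 7 single omissions for Heg1 (highest adjusted p = 0.092, without WT lithium female 1), in 8 for Acvrl1 (0.12, without HT lithium male 3) and in 2 for Rflnb (0.072, without HT lithium female 4). The sixth, Npy (-0.26, adjusted p = 0.025), a neuropeptide of interneurons, was chosen after its values were seen. The interaction values did not pass the test for Tph2 (-0.93, adjusted p = 0.29), Npy (-0.16, adjusted p = 0.42) and Rflnb (-0.12, adjusted p = 0.63) with lithium, or for Grin3a (0.10, adjusted p = 0.88) with fluoxetine. The 6 calls became 10 without HT lithium female 2, 3 without WT lithium female 3 or WT lithium male 2, and 2 without HT lithium female 4 or HT lithium male 3. They were 13 with DESeq2 or without the 14 libraries with olfactory or striatal transcripts, 16 in the fit of the compared groups alone, 14 with length and GC slopes and 3 with the tissue scores as covariates.

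Among gene lists, endothelial and pericyte markers were lower in HT than in WT under lithium (26 of 28, median -0.13, adjusted p = 1.2e-08, or adjusted p = 0.36 with an estimated correlation). So were cholesterol biosynthesis genes (24 of 24, median -0.08, adjusted p = 9.4e-09, or adjusted p = 0.36 with an estimated correlation). Olfactory bulb and migrating neuroblast markers were higher in the same HT libraries (15 of 17, median 0.69, adjusted p = 1.6e-05, or adjusted p = 0.63 with an estimated correlation). Under fluoxetine, glucocorticoid-responsive genes (19 of 20, median -0.17, adjusted p = 1.5e-07) and astrocyte markers (24 of 25, median -0.08, adjusted p = 4.1e-08) were lower in HT than in WT. Blood cell transcripts were higher (9 of 9, median 0.55, adjusted p = 2.1e-06), with mean scores of 0.601 ± 0.253 (SD, n = 5) in HT against -0.119 ± 0.533 (n = 5) in WT males but -0.345 ± 0.445 (n = 4) against -0.375 ± 0.258 (n = 4) in females. These 3 lists each had adjusted p = 0.40 with an estimated correlation.

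Within the sexes, lithium called Pnck in all 4 sex and genotype combinations, at -0.43 in WT females (adjusted p = 0.012), -0.43 in WT males (adjusted p = 0.015), -0.45 in HT females and -0.48 in HT males. In WT females 142 genes were called, 104 higher and 38 lower, with Frat1 (-0.68, adjusted p = 0.00036), Ctnnb1 (-0.21), the cytoskeletal protein Myadm (0.34) and Atxn2, an RNA binding protein (0.20), among them. In WT males 37 genes were called, including Ncdn (0.18), Polr2m (0.19), the hyaluronan synthase Has3 (0.68), Serpina3n (0.31) and the pseudogene Tpt1-ps3 (-1.04). In HT females 176 genes were called, including Ctnnb1 (-0.26, adjusted p = 2.9e-05), Cpeb1 (0.30), Tmem91 (-0.57) and Il18bp, a binder of interleukin-18 (0.54). In HT males 97 genes were called, including Ctnnb1 (-0.25), Eif4h (-0.26, adjusted p = 0.00011), the sorbitol dehydrogenase Sord (0.33) and Arpc4 (-0.29). In the fit of the compared groups alone the calls for lithium were 0 in WT females, 30 in WT males, 1 in HT females and 19 in HT males. They were 755, 223, 13 and 5 with length and GC slopes and 11, 4, 1 and 236 without the 14 libraries with olfactory or striatal transcripts. Fluoxetine called Kcnk6, a potassium channel (0.60 ± 0.106 SE, adjusted p = 0.012), and 2 unnamed transcripts in WT females. It called 0 genes with limma in WT males (1298 at an unadjusted p under 0.05, with 0 by edgeR and voom and 1 by DESeq2, smallest p for Rbm17 at 0.19, adjusted p = 0.28). It called 0 in HT females (1861, with 0 by edgeR and voom and 8 by DESeq2, Mvk at -0.33, adjusted p = 0.077) and 0 in HT males (778, with 0 by edgeR and voom and 1 by DESeq2, Stard4 at -0.37, adjusted p = 0.54).

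The differences between females and males were tested for each effect and limma called 0 genes in all 5. For the genotype effect 364 genes had an unadjusted p under 0.05 (0 called by edgeR, voom and DESeq2), with the smallest p at Fam205a2 (-7.04 ± 2.025 SE, adjusted p = 1). For fluoxetine in WT there were 852 (0 by edgeR and voom, 3 by DESeq2), led by Kcnk6 (0.63, adjusted p = 0.97). For fluoxetine in HT there were 1061 (0 by edgeR and voom, 4 by DESeq2), led by Isg20, an interferon-induced exonuclease (-1.6, adjusted p = 0.10), and 6 genes were called without HT fluoxetine female 1 or HT vehicle female 4 and 5 without WT fluoxetine male 1. For lithium in WT there were 1172 (0 by edgeR, voom and DESeq2), led by Lgals8 (-0.33, adjusted p = 0.52), with 1 gene called without WT lithium male 3. For lithium in HT there were 481 (0 by edgeR and voom, 1 by DESeq2), led by Gfpt1 (0.22, adjusted p = 1).

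The counts within a sex rested on single libraries, and those that moved each by over 1.5 times were as follows. The vehicle genotype effect in females, 1 gene, became 7 without HT vehicle female 1 and 2 without HT fluoxetine female 3, HT lithium female 2, HT vehicle female 2, WT lithium male 2 or WT vehicle male 3. Fluoxetine in WT females, 3 genes, became 6 without WT fluoxetine female 1 and 0 without WT fluoxetine female 2 or 3 or WT vehicle female 4. Fluoxetine in WT males became 1 without WT fluoxetine male 4. Fluoxetine in HT females became 6 without HT fluoxetine female 1, 5 without WT fluoxetine male 5, 2 without HT vehicle female 4 and 1 without HT fluoxetine female 3 or 4, and in HT males 1 without HT vehicle male 2. Lithium in WT males, 37 genes, became 65 without WT fluoxetine male 5, 59, 7 and 2 without WT lithium male 2, 4 and 5, and 4, 12 and 5 without WT vehicle male 1, 3 and 4. Lithium in HT females, 176 genes, became 381 without WT fluoxetine male 5, 336, 35, 74 and 17 without HT lithium female 1, 3, 4 and 5, and 94, 26 and 43 without HT vehicle female 2, 3 and 5. Lithium in HT males, 97 genes, became 182 without WT fluoxetine male 5, 50, 57, 8 and 27 without HT lithium male 1, 2, 3 and 4, and 6, 6, 56 and 39 without HT vehicle male 1, 2, 4 and 5. Lithium in WT females, 142 genes, was moved by 40 libraries. It was 29, 45, 14 and 4 without WT lithium female 1, 2, 3 and 4, and 741, 19, 3, 221 and 9 without WT vehicle female 1, 2, 3, 4 and 5. It was 82, 69, 87, 73 and 91 without WT lithium male 1, 2, 3, 4 and 5, and 88 and 76 without WT vehicle male 1 and 4. It was 77, 68, 74 and 83 without WT fluoxetine female 1, 2, 3 and 4, 253, 268 and 265 without WT fluoxetine male 1, 2 and 5. Omitting other libraries gave 75 without HT fluoxetine female 2, and 87, 70, 76, 64 and 68 without HT fluoxetine male 1, 2, 3, 4 and 5. Further values were 74 and 78 without HT lithium female 1 and 2, 72, 66, 85 and 84 without HT lithium male 1, 2, 4 and 5, 234 and 71 without HT vehicle female 1 and 2, and 80, 85 and 82 without HT vehicle male 1, 2 and 5.

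Markers of neighbouring brain regions varied between libraries within groups. Doc2g, expressed in the olfactory bulb, ran from 106 to 2957 over the 56 libraries, and Drd2, the dopamine receptor of striatal neurons, from 20.4 to 734. The olfactory score was above 1 in 9 libraries and the striatal score in 5, which were the 14 libraries left out in the alternative named above. The principal component with the largest share of the variance, 8.63%, followed the olfactory score, and the third, 4.29%, the striatal score. The olfactory score averaged -0.773 ± 0.125 (SD, n = 4) in WT lithium females and -0.287 ± 0.749 (n = 5) in WT lithium males, against 0.154 ± 1.15 (n = 5) in WT vehicle females and -0.187 ± 0.665 (n = 4) in WT vehicle males. The olfactory list was lower under lithium in WT (15 of 17, median -0.49, adjusted p = 0.044, or adjusted p = 0.73 with an estimated correlation).

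**Figure D5:**
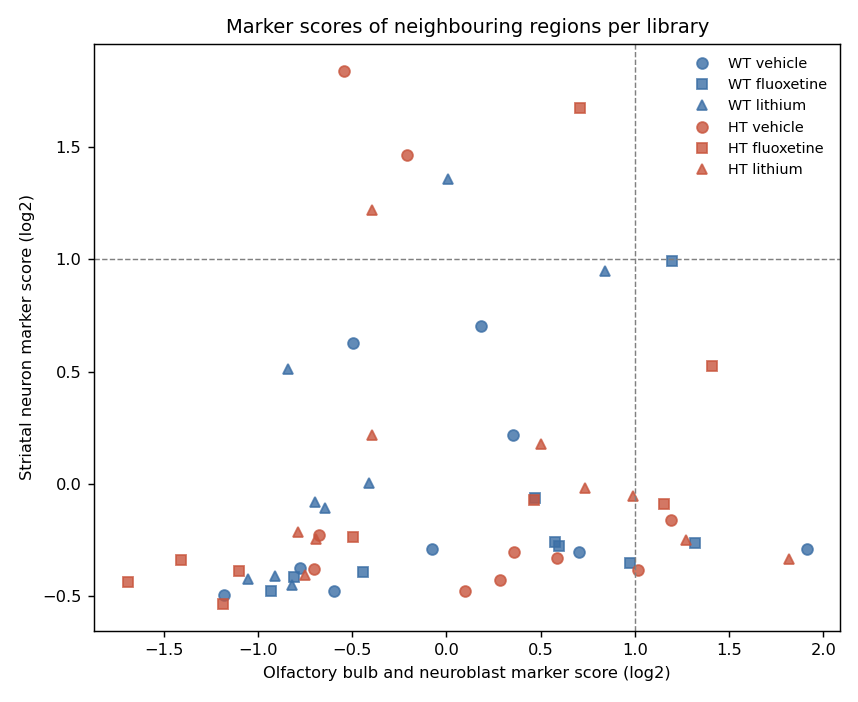
Olfactory marker score and striatal marker score of the 56 libraries, as mean log2 deviation over each marker list, with points for libraries by group and the value of 1 above which a library was left out in an alternative. The olfactory score is above 1 in 9 libraries and the striatal score in 5.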

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

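Of the tests in this part, the covariates for tissue scores and for length and GC slopes were chosen after the data had been seen, as were the patterns weighed.

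Each of the 12 groups was tested on 8 measures for a single library far from the others, by Dixon's criterion. Of these 96 tests 8 found one, where chance gives about 1 in 20 tests. WT vehicle female 5 held 25.1 M reads against at least 28.5 M in its group, and its blood cell score was -0.281 against 0.198 to 0.373. The striatal score was 1.67 in HT fluoxetine male 5, 0.991 in WT fluoxetine male 1, 1.84 in HT vehicle female 3 and 1.46 in HT vehicle male 3, while all other libraries of those groups lay below 0. The ribosomal protein score was -0.247 in HT lithium male 3 (others -0.101 to -0.0683) and -0.130 in HT vehicle male 5 (others 0.0637 to 0.118). The slope on GC content was not among the 8 measures. It was -0.138 in WT fluoxetine male 5, against -0.0183 to 0.0387 in the others of its group. Leaving this library out moved counts of comparisons without it, such as lithium in HT from 1560 to 1815 and the vehicle genotype effect from 1 to 12.

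The genotypes differed in the median response of 14 lists to fluoxetine, by camera on the interaction at the preset correlation. The difference (HT minus WT, log2) was -0.22 for glucocorticoid-responsive genes, -0.10 for heat shock and unfolded protein response, -0.0917 for cholesterol biosynthesis, -0.0865 for neuropeptides, -0.0749 for serotonin signalling and -0.0611 for astrocyte markers. It was -0.0572 for cytosolic ribosomal proteins, -0.0468 for oxidative phosphorylation, -0.0425 for mitochondrial ribosomal proteins and -0.0281 for the proteasome. It was -0.46 for olfactory bulb and migrating neuroblast markers, 0.0611 for voltage-gated calcium channels, 0.0327 for chromatin regulators and 0.0217 for autism risk genes. Under lithium 12 lists differed: cholesterol biosynthesis by -0.17, neuropeptides by -0.14, the presynaptic vesicle cycle by -0.0593, the proteasome by -0.0587, heat shock and unfolded protein response by -0.0523, mitochondrial ribosomal proteins by -0.0518 and oxidative phosphorylation by -0.0376. In the other direction were olfactory bulb and migrating neuroblast markers by 0.60, meningeal and fibroblast markers by 0.18, interferon response by 0.10, chromatin regulators by 0.0745 and microglia markers by 0.0612. None of these 26 calls held with an estimated correlation (adjusted p of 0.41 to 0.77 for fluoxetine and 0.47 to 0.69 for lithium, with an estimated correlation).

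Ribosomal protein genes were lower under lithium in both genotypes. In WT the list mean differed by -0.140. The upper 95% bound of the difference stayed below 0 with length and GC slopes (-0.0491) and with olfactory and striatal scores (-0.0526) as covariates. This argues against each of these as the whole cause in WT. For pseudogenes the measure was log2 of summed values. It differed by -0.134 for the genes alone and by -0.133 with pseudogenes whose names hold -ps added (upper bound -0.0517). Those pseudogenes alone differed by -0.0969 (95% interval -0.242 to 0.0483). This argues against a shift of reads to them as the whole cause, but pseudogenes under other names were not added. In HT the bound stayed below 0 with the tissue scores (-0.0785) and, for the log2 sum, with the same pseudogenes added (-0.0772). With length and GC slopes, however, the HT difference moved from -0.157 ± 0.0393 to -0.0604 ± 0.0323 (SE), with an upper bound of 0.00476, because the difference shrank more than its error did, so a length or GC trend of the libraries may account for it in HT. The length slopes ran from -0.0529 to 0.00283 in HT vehicle and from -0.0154 to 0.0530 in HT lithium libraries. They come from expression in the same libraries, so this fit cannot tell such a trend from an effect of lithium. An effect of lithium itself was not tested apart from these and stays open in both genotypes.

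Cholesterol biosynthesis genes were lower under fluoxetine in HT by -0.207 in the list mean. The upper 95% bound stayed below 0 with length and GC slopes (-0.113), with olfactory and striatal scores (-0.140) and with astrocyte and oligodendrocyte scores as covariates (-0.137). These tests argue against a length or GC trend, the dissection or a lower share of those cells as the whole cause. What stays open is a response to fluoxetine, offered as a hypothesis since the pattern was found and tested on the same libraries. A litter effect stays open too, since the labels name no dams and a shared dam could give the same pattern. High values in the HT vehicle libraries, where this list was above WT vehicle, may be a part of the difference. The list was also lower under fluoxetine in WT, a comparison without those libraries, but that call was lost with an estimated correlation.

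Microglia markers were lower under lithium, by -0.154 in WT and -0.103 in HT in the list mean. The upper 95% bounds stayed below 0 with olfactory and striatal scores as covariates (-0.0735 in WT, -0.0225 in HT), and with the meningeal score (-0.0129 in WT, -0.00823 in HT), although the latter reduced the WT difference to -0.0964. Fewer microglia would lower all markers alike, but the markers differed by more than their standard errors (Cochran's Q, a chi-square test over the 24 markers, p = 4.2e-05 in WT and p = 0.0016 in HT), which argues against a uniform loss of cells as the whole cause. A change of state of these cells may remain, as may less meningeal tissue as a part of the WT difference, and neither was tested further.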

How the results depend on the processing

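Tests chosen after the data were seen were edgeR, DESeq2, the tissue scores, the length and GC slopes, the fit without the 14 libraries, the exact permutation of list means and all settings of the pooled effect. No called gene among those named changed sign when a single library was left out, though uncalled values near 0 did, such as that of Scn3a for the vehicle genotype effect in 9 omissions. The balance of lithium calls in WT turned, from 682 higher of 1016 to 316 of 794 with voom. The 25 counts of genes stayed within 1.5 times of their value in 24 with edgeR, TMM rescaling, no filter and either pseudocount, 22 with voom, 17 with the tissue scores, 14 with the slopes, 13 without the 14 libraries, 12 with only the groups compared and 6 with DESeq2. The fit of the compared groups alone uses fewer libraries, and the fit without the 14 libraries leaves groups as small as 2. For all settings below the cause was not tested. Depth was 24.3 to 36.4 M reads, and which genes it limits was not tested beyond the 310 left out by the filter.

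With DESeq2 the counts were 34 for the vehicle genotype effect (1 in the report), 2 in females and 2 in males, 123 for fluoxetine in WT (26), 20 in females and 1 in males, 16 for fluoxetine in HT (8), 8 in females and 1 in males, 483 and 120 for lithium in WT females and males (142, 37), 399 and 269 in HT females and males (176, 97), 13 for the genotype effect under lithium (6), 11 for the interaction with lithium (0), 50 for the pooled effect (27), and 3, 4 and 1 for the sex differences of fluoxetine in WT and HT and of lithium in HT (0). Lithium in WT females gave 55 with TMM rescaling, 45 with edgeR, 49 with voom, 92 with no filter and 90 with a pseudocount of 5. Voom gave 7 for fluoxetine in WT and 3 for the vehicle genotype effect, and a pseudocount of 0.5 gave 2 for that effect in females.

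With only the groups compared the counts were 9 for fluoxetine in WT, 0 in females, 1 in males and 1 for its sex difference, 19 for fluoxetine in HT and 1 in males, 0 for lithium in WT females, 1 and 19 for lithium in HT females and males, 0 and 2 for the vehicle genotype effect in females and males, and 1 and 16 for the genotype effects under fluoxetine and lithium. With length and GC slopes they were 57 for fluoxetine in WT, 5 for fluoxetine in HT, 1686, 755 and 223 for lithium in WT, its females and its males, 58, 13 and 5 for lithium in HT, its females and its males, 14 for the genotype effect under lithium, 2 under vehicle and 48 pooled. With the tissue scores they were 66 for fluoxetine in WT, 13 in HT, 75 for lithium in WT females, 319 and 191 for lithium in HT females and males, 13 for the genotype effect under vehicle, 3 under lithium and 64 pooled. Without the 14 libraries they were 8 for fluoxetine in WT and 0 in its females, 2 in HT and 1 in its females, 457, 11 and 4 for lithium in WT, its females and its males, 586, 1 and 236 for lithium in HT, its females and its males, and 2 and 13 for the genotype effect under vehicle and lithium.

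The replicate number as a block moved lithium in WT females to 496 and the sex difference of fluoxetine in HT to 6 and changed no other count of genes or lists by over 1.5 times. The numbers do not pair the samples: deviations of libraries with the same number correlated at 0.00258 on average over 133 pairs against -0.000521 for other numbers, and 12 of 56 libraries were closest to their own number.

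Leave-one-out ranges were 0 to 71 for fluoxetine in WT (females 0 to 6, males 0 to 1), 4 to 13 in HT (females 0 to 6, males 0 to 1, sex difference 0 to 6), 571 to 1226 for lithium in WT (females 3 to 741, males 2 to 65, sex difference 0 to 1), 985 to 1815 in HT (females 17 to 381, males 6 to 182), 1 to 35 for the vehicle genotype effect (females 1 to 7), 1 to 2 and 2 to 10 for those under fluoxetine and lithium, 17 to 42 pooled and 0 to 1 for the interaction with lithium. For called lists they were 4 to 10 for fluoxetine in WT, 6 to 17 in HT and 7 to 16 for the genotype effect under fluoxetine.

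Called lists fell to 1 for fluoxetine in HT and to 0 in the other 8 comparisons with an estimated correlation. Fry called 1 for fluoxetine in HT, 2 in WT, 7 for lithium in HT, 8 in WT and 0 in the others, and the exact permutation called 1, 1, 6, 3 and, for the 3 genotype effects, 0. Fry tests whether a list moves on balance, not against other genes.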

Other observations

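Of the tests in this part, the genotype effect pooled over vehicle, fluoxetine and lithium was chosen after the separate results had been seen, as were its alternatives with edgeR, tissue scores and slopes.

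Averaged over the 3 treatments, HT cortex differed from WT in 27 genes, 9 higher and 18 lower. Scn2a fell by 0.53 in 29 of 29 HT libraries (adjusted p = 3.7e-25). Other genes that fell were Heg1, an endothelial receptor (-0.17, adjusted p = 2.4e-05, 29 of 29), Acvrl1, a receptor of the TGF-beta family in endothelial cells (-0.16, adjusted p = 0.0022), and Abcc9, a potassium channel subunit of pericytes (-0.22, adjusted p = 0.015). Grin3a, an NMDA receptor subunit of the developing cortex, rose by 0.12 (adjusted p = 3.2e-04, 28 of 29), Npy, a peptide of interneurons, fell by 0.18 (adjusted p = 0.0011, 26 of 29), and Mapk3, the kinase ERK1, rose by 0.16 (adjusted p = 0.0016). Ngb, the oxygen-binding neuroglobin, rose by 0.42 (adjusted p = 0.0035, on a mean of 69.8), Fxyd6 rose by 0.12 (adjusted p = 0.0069), and Slc22a3, a transporter of monoamines, rose by 0.34 (adjusted p = 0.0069). Rflnb (-0.23, adjusted p = 3.2e-04), Myh7 (-0.25, adjusted p = 3.8e-04) and Tmem114 (-0.44, adjusted p = 0.0036) fell. These genes were picked by eye from the 27, and no gene list was tested for the pooled effect. The mean endothelial and pericyte marker score was lower in HT than in WT in both sexes under vehicle and lithium and in fluoxetine females. For lithium females it was -0.137 against 0.00641. In fluoxetine males it was not lower (0.00607 against -0.000834). Whether this score goes with the vessel genes above was not tested.

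Of the 27 genes, 16 were called in all 56 fits that left out a single library, and the count ran from 17 without WT fluoxetine female 3 to 42 without HT fluoxetine female 1, with 41 without WT lithium male 5. Of 100 splits of the libraries only the real one called as many, with 0 in the highest other. This argues against chance for the count, but the effect was chosen after the separate results had been seen. The splits also exchanged single libraries, so pups that may share a dam were not kept together.

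Genes carried along with the mutated allele from another strain might differ between genotypes near Scn2a. Within 10 Mb of Scn2a, 9 of 101 tested genes (8.91%) had an unadjusted p under 0.05 for the pooled effect, against 1425 of 17665 elsewhere (8.07%), a one-sided Fisher's exact test giving p = 0.430. Linked alleles and their absence cannot be told apart here, since a few linked differences would be hidden among 101 genes and the labels do not give the origin of the allele.

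Each count of called genes was set against 100 splits of the same libraries, the real split included. As many genes were called in 5 splits for the vehicle genotype effect (1 gene, highest other 31) and in 6 for fluoxetine in WT (26, highest other 327), so chance could not be excluded for these counts. A count does not regard which gene was called, and the gene under vehicle was Scn2a, with an adjusted p of 4.6e-15 and HT and WT ranges that did not overlap, so the value for the count does not bear on the call of Scn2a itself. For lithium in WT (1016 genes) and in HT (1560 genes) only the real split called as many, 1 of 100 each, with 267 and 472 in the highest others, and for the genotype effect under lithium (6) 1, the highest other 1. A share of 1 is the lowest that 100 splits can give. For the genotype effect under fluoxetine (2 genes) 4 splits called as many, the highest other 4. Because 1 of these 2 genes is Scn2a, which differs by the genotype itself, that value says nothing on Grin3a. For fluoxetine in HT (8 genes) 3 splits called as many, the highest other 24, and for lithium in WT females (142) 4, the highest other 585. No share below 5 of 100 in this part was adjusted over the 25 comparisons. The splits exchanged single libraries, so pups that may share a dam were not kept together. Chance is therefore argued against only weakly for all counts with such shares. Within a sex the share was 1 for lithium in WT males (37 genes, highest other 2), HT females (176, highest other 24) and HT males (97, highest other 2). It was also 1 for fluoxetine in WT females (3 genes, highest other 2), a count that was 0 without WT fluoxetine female 2 or 3 or WT vehicle female 4. With only the groups compared, 0 genes were called for fluoxetine in WT females and 1 for lithium in HT females. Chance could not be excluded for the vehicle genotype effect in females (1 gene, 9 splits, highest other 914) or males (1, 14, highest other 30) as counts, where the gene was again Scn2a. Where 0 genes were called, all 100 splits called as many, with highest others of 97 and 196 for the interactions with fluoxetine and lithium, 57 for fluoxetine in WT males, 146 and 1 in HT females and males, and 5, 157, 112, 3 and 316 for the sex differences of the genotype effect, fluoxetine in WT and HT, and lithium in WT and HT. Splits that called several times the real count, such as 327 against 26 and 914 against 1, point to a structure of the samples other than their groups, and its source was not tested.

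For counts of called lists chance could not be excluded in any comparison. As many lists were called in 66 of 100 splits for the vehicle genotype effect (10 lists, highest other 26), 84 for fluoxetine in WT (6, highest other 23), 52 for fluoxetine in HT (13, highest other 24), 30 for lithium in WT (15, highest other 27) and 39 for lithium in HT (13, highest other 26). The shares were 20 for the genotype effect under fluoxetine (13, highest other 15), 11 under lithium (16, highest other 26), 27 for the interaction with fluoxetine (14, highest other 22) and 44 for that with lithium (12, highest other 27).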
